A study of Homo sapiens with 15 samples.

How the data were processed

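The study measured gene expression in MDA-MB-231, an established human breast cancer cell line with a mesenchymal phenotype, on 15 Affymetrix arrays. Cells were grown for 3 days in RPMI medium with serum, and the compound or the ethanol vehicle was added at plating. Total RNA was extracted with Trizol, amplified from an oligo-dT primer and labelled with biotin. The arrays fall into 7 groups: 6 hexosamine analogs with 2 arrays each and an ethanol control (EtOH, 0.4%) with 3 arrays, which the series design calls independent biological replicates.

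The deposited table holds 54675 probe sets, and its unit is intensity: a summarised signal per probe set on a linear scale, made by the authors with GCOS and MAS5 per the submitters' processing notes. Software versions, the scaling target and detection calls are not given in the sources used here. The values themselves show a 2% trimmed mean of 150.0 on every array, so the arrays had been scaled to a common mean before deposition. Array medians lay within 1.22-fold of each other, below the 1.5-fold limit set for further scaling, so the deposited scaling was kept. Gene symbols came from the platform annotation and were updated through Entrez identifiers with an NCBI RefSeq table for assembly GRCh38.p14. Of the probe sets, 62 were controls, 41091 carried a single gene symbol, 1801 carried several and 11721 had no symbol.

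Values were analysed as log2 of the intensity plus 16. Control probe sets were left out, and probe sets whose mean log2 value lay above the 40th percentile were kept, which left 32768. Each gene was represented by its brightest probe set with a single symbol, giving 14207 genes. Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in a single fit of all 7 groups, with 8 residual and 6.41 prior degrees of freedom. There were 12 contrasts: each of the 6 analogs against the vehicle, and 6 between analogs. P-values were adjusted by Benjamini-Hochberg within each contrast, with an adjusted p of 0.05 as threshold. Adjustment over all 12 contrasts together is given as a second count. All p-values rest on 2 or 3 arrays per group, with the spread pooled over the groups. Log2 changes are given with the standard error (SE) of the fit, and array signals as mean with standard deviation (SD). A fold is 2 to the power of the log2 change, so it includes the 16 added to each value.

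Gene groups were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 41 lists within each contrast. Beside each call stands the adjusted p of the same test with the correlation estimated from the data, and the median without any array that moved it by over 1.5 times while the call held. The 41 lists hold 1013 genes, of which 918 had a probe set with a single symbol. Of the lists 4 hold markers of cell types that the cultures should not contain: leukocytes, erythroid cells, endothelium and luminal breast epithelium. For each list, members past the threshold were counted over all genes tested and again adjusted over the list alone. The lists, contrasts, tests, the alternative settings and the rule for named genes were fixed before the data were examined, except for a covariate for the bright end of the arrays, a reading of called genes in other contrasts and a simulated overlap of lists of equal length, all added after seeing the data. That rule names, per vehicle contrast, the 10 largest rises and 10 largest falls past the threshold whose arrays do not overlap, and the 5 and 5 largest between analogs. It adds the 2 to 4 members of each called list that moved most in the list's direction, and the 3 genes with the smallest p where no gene passed. CDKN1A, MUC1, CXCR4, MMP9, RELA, CCND1, BIRC5 and GNE were followed in every vehicle contrast.

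Overlap between analogs was compared with 50 simulations of unchanged groups that share the vehicle arrays, and with the overlap of independent lists. Counts of genes past the threshold, list calls, named genes past it and the overlap were recomputed under these alternatives: quantile normalization, a pseudocount of 1 or of 64, no filter or a filter at the 60th percentile, no intensity trend, array weights, the mean of all probe sets of a gene, the replicate number as a block, an adjusted p of 0.01 for the overlap, and each array left out in turn. With an array left out, a group with 1 array left was assumed to vary like the others. The method was tested on simulated data with 200 changed genes of 14207 in each of 10 runs. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.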

Results

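Gene expression was profiled in MDA-MB-231 breast cancer cells after 3 days with 1 of 6 acylated hexosamines or with ethanol vehicle. Ac4ManNLev (75 µM) is a mannosamine that carries a levulinoyl group on its nitrogen and 4 acetyl esters. C1OH-Ac3ManNAc (100 µM) is N-acetylmannosamine with 3 acetyl esters and a free hydroxyl at C1. Butyrate esters replace acetate in C1OH-But3GalNAc (50 µM), C1OH-But3GlcNAc (40 µM) and C1OH-But3ManNAc (30 µM), built on N-acetylgalactosamine, N-acetylglucosamine and N-acetylmannosamine. C6OH-But3ManNAc (30 µM) carries the free hydroxyl at C6. Each analog had 2 arrays and the vehicle 3. The doses differ between analogs except for the C1OH and C6OH forms of But3ManNAc, both at 30 µM.

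Median signals ran from 33.3 to 40.7, the GAPDH 3'/5' signal ratio from 0.846 to 0.915, the ACTB ratio from 1.08 to 1.18, array weights from 0.616 (EtOH 3) to 1.52 (EtOH 1) and the signal of a 28S ribosomal RNA control probe set from 332 to 657. Arrays of the same group correlated with a median r of 0.985 over 9 pairs, and arrays of different groups with a median of 0.985 over 96 pairs, both computed across genes. At most 0.00366% of probe sets had equal values in any pair of arrays. The bright-end signal, which the brightest 0.1% of probe sets exceed, was 7761 in EtOH 1, 7967 in EtOH 2 and 10342 in EtOH 3, and reached 10821 in C1OH-But3ManNAc 1. The median log2 change of all genes stayed within -0.02 and 0.01 in the vehicle contrasts. The median 95% interval of a gene's log2 change had a half-width of 0.30 against vehicle and 0.33 between analogs. Single-gene values in parentheses are log2 changes ± SE.

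Ac4ManNLev was compared with vehicle to show which transcripts respond to the levulinoyl analog. At 75 µM it raised 16 genes and lowered 9 of 14207. AKR1C3, an aldo-keto reductase, was higher by 1.93-fold (0.95 ± 0.12, adjusted p = 0.00464) and NQO1, a quinone reductase, by 1.52-fold (0.61 ± 0.07, adjusted p = 0.00464), with NQO1 signals of 3151 ± 91.6 against 2064 ± 68.3 (SD, 2 and 3 arrays). The long non-coding RNA UCA1 was lower by 2.07-fold (-1.05 ± 0.14, adjusted p = 0.00543), the metastasis suppressor KISS1 by 1.78-fold (-0.83 ± 0.15, adjusted p = 0.0448) and ID1, an inhibitor of basic helix-loop-helix transcription factors, by 1.72-fold (-0.79 ± 0.10, adjusted p = 0.00464). Other rises were SPANXB1 1.83-fold, TTC14 1.72-fold, LPXN 1.68-fold, CDC42EP2 1.55-fold, LINC00973 1.54-fold, PIR 1.54-fold, NAV3 1.5-fold and MYEOV 1.46-fold, with 1 of the 2 LPXN probe sets above 0. Other falls were HMGCS1 1.65-fold, MATN2 1.64-fold, AQP3 1.45-fold, FDPS 1.39-fold, LOXL4 1.39-fold and PLEKHA2 1.31-fold.

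The cholesterol biosynthesis list fell with Ac4ManNLev (median -0.24, adjusted p = 1.65e-08, adjusted p = 0.0607 with an estimated correlation). Of its 19 members 2 fell over all genes and 12 fell over the list alone, among them HMGCS1 (-0.73 ± 0.13), the synthase ahead of HMG-CoA reductase, and FDPS (-0.48 ± 0.09), while MSMO1 (-0.44 ± 0.10) and INSIG1 (-0.32 ± 0.10) did not pass over all genes. The NRF2 oxidative stress list rose (median 0.15, adjusted p = 1.94e-06, adjusted p = 0.0648 with an estimated correlation; median 0.23 without EtOH 2). Of its 21 members 3 rose over all genes and 6 rose over the list alone, with AKR1C3 (0.95 ± 0.12), PIR (0.62 ± 0.11) and NQO1 (0.61 ± 0.07) past the threshold and SLC7A11 (0.54 ± 0.13) not. Fatty acid synthesis fell (median -0.13, adjusted p = 0.0324, adjusted p = 0.215 with an estimated correlation). Among 12 members 0 passed over all genes and 2 fell over the list alone, with values of SCD (-0.49 ± 0.10) and FASN (-0.45 ± 0.09). The unfolded protein response and ATF4 list rose (median 0.11, adjusted p = 0.00442, adjusted p = 0.0648 with an estimated correlation; median 0.06 without EtOH 2). Of 31 members 0 passed over all genes and 3 rose over the list alone, with values of PPP1R15A (0.51 ± 0.10) and ASNS (0.50 ± 0.13). Immediate early genes rose (median 0.08, adjusted p = 0.00884, adjusted p = 0.111 with an estimated correlation; median 0.13 without Ac4ManNLev 2). Among 22 members 1 rose over all genes and 2 rose over the list alone, including DUSP5 (0.50 ± 0.07), a phosphatase of ERK.

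A further 5 lists shifted with Ac4ManNLev while no member passed over all genes or over the list alone. Proteasome subunits rose (median 0.12, adjusted p = 0.000215, adjusted p = 0.406 with an estimated correlation; median 0.19 without EtOH 3), with 21 of 25 members above 0 and PSMB7 (0.35 ± 0.11) and PSMB2 (0.25 ± 0.10) farthest. The MYC and ribosome biogenesis list rose (median 0.08, adjusted p = 0.00884, adjusted p = 0.361 with an estimated correlation), with 19 of 24 members above 0 and values of ODC1 (0.28 ± 0.09) and MYC (0.23 ± 0.09). Mucins fell (median -0.18, adjusted p = 0.00884, adjusted p = 0.109 with an estimated correlation), with 9 of 10 members below 0 and values of MUC13 (-0.70 ± 0.25), MUC4 (-0.59 ± 0.26) and MUC1 (-0.57 ± 0.23). Chemokines and their receptors fell (median -0.25, adjusted p = 0.00884, adjusted p = 0.109 with an estimated correlation), with 12 of 14 members below 0 and values of CXCL14 (-0.54 ± 0.24), CXCL3 (-0.51 ± 0.25) and CXCL8 (-0.39 ± 0.13). Mesenchymal markers fell (median -0.15, adjusted p = 0.0101, adjusted p = 0.0971 with an estimated correlation; median -0.10 without EtOH 1), with 18 of 24 members below 0 and values of TAGLN (-0.62 ± 0.17) and FN1 (-0.41 ± 0.13). Of the 25 genes past the threshold, 16 also passed when p was adjusted over all 12 contrasts, and 1362 genes had an unadjusted p below 0.05. The count was 0 without Ac4ManNLev 2, 6 without Ac4ManNLev 1 (3 rose) and 15 without EtOH 1. Calls ended in 8 or more of the 15 leave-one-out fits for FDPS, PIR (13), HMGCS1, LPXN, PLEKHA2 (11) and KISS1 (10). List calls ended, with these medians, without Ac4ManNLev 2 (chemokines -0.15, fatty acid synthesis -0.04, mesenchymal -0.14, mucins -0.24, MYC 0.07), without EtOH 2 (fatty acid synthesis -0.14, MYC 0.07), without EtOH 3 (fatty acid synthesis -0.13), without Ac4ManNLev 1 (immediate early 0.01) and without EtOH 1 (immediate early 0.06, MYC 0.07).

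C1OH-Ac3ManNAc carries acetate in place of butyrate, and at 100 µM it raised 5 genes and lowered 2. The rises were SPANXB1, a cancer-testis antigen, at 1.75-fold (0.81 ± 0.12, adjusted p = 0.0401), CDC42EP2, an effector of CDC42, at 1.47-fold (0.55 ± 0.09, adjusted p = 0.0435), G0S2, an inhibitor of triglyceride lipase, at 1.44-fold (0.53 ± 0.08, adjusted p = 0.0401), and LYRM1 1.41-fold and NAV3 1.4-fold. CASP10, an initiator caspase, was lower by 2.71-fold (-1.44 ± 0.22, adjusted p = 0.0401), with signals of 27.5 ± 0.626 against 103 ± 19.01 and the same sign in 2 of its 3 probe sets. ID1 was lower by 1.73-fold (-0.79 ± 0.10, adjusted p = 0.0207).

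Cholesterol biosynthesis fell with C1OH-Ac3ManNAc (median -0.22, adjusted p = 2.72e-07, adjusted p = 0.0472 with an estimated correlation). Of its 19 members 0 passed over all genes and 10 fell over the list alone, with values of HMGCS1 (-0.47 ± 0.13), EBP (-0.47 ± 0.14) and MSMO1 (-0.39 ± 0.10). Immediate early genes rose (median 0.12, adjusted p = 5.53e-05, adjusted p = 0.0472 with an estimated correlation). Of 22 members 0 passed over all genes and 2 rose over the list alone, with values of MYC (0.39 ± 0.09) and DUSP5 (0.38 ± 0.07). The unfolded protein response and ATF4 list rose (median 0.13, adjusted p = 0.00192, adjusted p = 0.0472 with an estimated correlation). Among 31 members 0 passed over all genes and 1 rose over the list alone, with values of PPP1R15A (0.48 ± 0.10) and ASNS (0.39 ± 0.13). The NRF2 list rose (median 0.20, adjusted p = 5.53e-05, adjusted p = 0.117 with an estimated correlation; median 0.11 without C1OH-Ac3ManNAc 2). Of 21 members 0 passed over all genes and 5 rose over the list alone, with values of AKR1C3 (0.56 ± 0.12) and NQO1 (0.39 ± 0.07). Heat shock genes rose (median 0.14, adjusted p = 0.000355, adjusted p = 0.251 with an estimated correlation; median 0.22 without EtOH 3). Among 13 members 0 passed over all genes and 1 rose over the list alone, with values of HSPE1 (0.33 ± 0.09) and HSPB1 (0.29 ± 0.10). The MYC list rose (median 0.10, adjusted p = 0.00324, adjusted p = 0.384 with an estimated correlation; median 0.06 without EtOH 2). Of 24 members 0 passed over all genes and 1 rose over the list alone, with values of MYC (0.39 ± 0.09) and NPM1 (0.21 ± 0.13). TGF-beta response genes fell (median -0.15, adjusted p = 0.00899, adjusted p = 0.197 with an estimated correlation). Among 23 members 1 fell over all genes and 3 fell over the list alone, ID1 among them, while ID3 had a value of -1.0 ± 0.27.

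No member passed over all genes or over the list alone in 3 further lists that rose with C1OH-Ac3ManNAc. These were the cytosolic ribosomal proteins (median 0.21, adjusted p = 2.54e-09, adjusted p = 0.466 with an estimated correlation; median 0.12 without C1OH-Ac3ManNAc 2, 0.12 without EtOH 1 and 0.35 without EtOH 3), with 34 of 34 members above 0 and values of RPS7 (0.35 ± 0.13) and RPL8 (0.27 ± 0.14), the proteasome (median 0.14, adjusted p = 1.46e-05, adjusted p = 0.386 with an estimated correlation; median 0.21 without C1OH-Ac3ManNAc 1, 0.09 without C1OH-Ac3ManNAc 2 and 0.23 without EtOH 3), with values of PSMB2 (0.32 ± 0.10) and PSMB7 (0.26 ± 0.11), and oxidative phosphorylation (median 0.06, adjusted p = 0.0151, adjusted p = 0.701 with an estimated correlation; median 0.12 without C1OH-Ac3ManNAc 1 and 0.11 without EtOH 3), with values of NDUFB3 (0.34 ± 0.10) and NDUFA1 (0.29 ± 0.16). The ribosomal list moved with the bright end of the arrays, whose bright-end signal was 9433 and 10370.1 in the C1OH-Ac3ManNAc arrays, with 28S signals of 603 and 422. With that signal as a covariate, chosen after the array values were seen, the ribosomal median was -0.01 and the oxidative phosphorylation median -0.04. Of the 7 genes past the threshold, 6 passed over all 12 contrasts together, and 1280 had an unadjusted p below 0.05. The count was 0 without C1OH-Ac3ManNAc 2, EtOH 1 or EtOH 2, and 1, which fell, without EtOH 3 or any array of C1OH-But3GalNAc or C6OH-But3ManNAc. It was 2 without any array of Ac4ManNLev (1 rose) or C1OH-But3GlcNAc (0 rose) and 3 without C1OH-Ac3ManNAc 1. Calls ended in 8 or more of the 15 leave-one-out fits for CDC42EP2, G0S2, LYRM1, NAV3 (13), CASP10 (11) and SPANXB1 (10). Calls of lists ended, with these medians, without C1OH-Ac3ManNAc 2 (MYC 0.08, oxidative phosphorylation 0.02, unfolded protein response 0.10), without EtOH 1 (MYC 0.10, oxidative phosphorylation 0.03), without EtOH 2 (oxidative phosphorylation 0.03, TGF-beta -0.10) and without C1OH-Ac3ManNAc 1 (TGF-beta -0.22).

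C1OH-But3GalNAc, the galactosamine scaffold with butyrate, raised 39 genes and lowered 16 at 50 µM. Rises included EHF, an epithelial ETS transcription factor, at 1.92-fold (0.94 ± 0.11, adjusted p = 0.00197), EEF1A2, a translation elongation factor, at 1.77-fold (0.82 ± 0.09, adjusted p = 0.00181), and LAMB3, the laminin beta 3 chain, at 1.6-fold (0.68 ± 0.07, adjusted p = 0.00181). The neutrophil chemokine CXCL8 was higher by 1.67-fold (0.74 ± 0.13, adjusted p = 0.0273), with signals of 519.7 ± 41.8 against 306 ± 37.6. The other largest rises were DNAAF3 2.25-fold, APCDD1L 1.79-fold, OTUB2 1.76-fold, EGR1 1.73-fold, EREG 1.61-fold and G0S2 1.6-fold. Among the falls, CDC25A, a phosphatase that drives entry into S phase, was lower by 2.51-fold (-1.33 ± 0.18, adjusted p = 0.00705), and ADAM12, a membrane protease, by 3.1-fold (-1.63 ± 0.26, adjusted p = 0.0151), with signals of 12.2 ± 2.65 against 71.1 ± 4.42. The mean ADAM12 signal with the analog lay below the 40th percentile of every array, which ran from 21.5 to 26.4. Other falls were NF2 2.73-fold, LOC730098 2.72-fold, ID3 2.72-fold, SLC45A2 2.24-fold, PLA2G2A 2.12-fold, HLA-F-AS1 1.99-fold, LOC101927143 1.87-fold and FGA 1.87-fold. The sign was shared by 2 of 3 probe sets for EGR1, ADAM12 and CDC25A and by 1 of 2 for FGA. The ID3 log2 change of -1.44 was -0.88 without C1OH-But3GalNAc 2.

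NF-kB target genes rose with C1OH-But3GalNAc (median 0.25, adjusted p = 1.39e-08, adjusted p = 0.0295 with an estimated correlation). Of 23 members 4 rose over all genes and 9 rose over the list alone, and the 4 that passed were CXCL8, the cytokine IL6 (0.63 ± 0.10), the adhesion molecule ICAM1 (0.55 ± 0.10) and TNFAIP2 (0.52 ± 0.09). Immediate early genes rose (median 0.14, adjusted p = 1.87e-05, adjusted p = 0.0403 with an estimated correlation). Among 22 members 3 rose over all genes and 4 rose over the list alone, the former being EGR1 (0.79 ± 0.15), DUSP5 (0.56 ± 0.07) and DUSP1 (0.47 ± 0.09). Glycolysis and hypoxia response genes rose (median 0.10, adjusted p = 4.58e-06, adjusted p = 0.0821 with an estimated correlation; median 0.06 without EtOH 2 and 0.18 without EtOH 3). Of 32 members 2 rose over all genes and 4 rose over the list alone, the former being PFKFB4 (0.66 ± 0.12) and NDRG1 (0.47 ± 0.08). The NRF2 list rose (median 0.17, adjusted p = 0.00017, adjusted p = 0.102 with an estimated correlation). Among 21 members 2 rose over all genes and 2 rose over the list alone, the former being AKR1C3 (0.63 ± 0.12) and NQO1 (0.39 ± 0.07). Cholesterol biosynthesis fell (median -0.20, adjusted p = 9.4e-05, adjusted p = 0.0821 with an estimated correlation). Of 19 members 0 passed over all genes and 6 fell over the list alone, with values of HMGCS1 (-0.46 ± 0.13), FDPS (-0.33 ± 0.09) and ACAT2 (-0.31 ± 0.07). Extracellular matrix genes rose (median 0.11, adjusted p = 0.0072, adjusted p = 0.187 with an estimated correlation). Among 32 members 1 rose over all genes and 2 rose and 1 fell over the list alone, LAMB3 among them and COL6A2 with a value of 0.57 ± 0.21.

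Epithelial markers rose with C1OH-But3GalNAc (median 0.04, adjusted p = 0.0428, adjusted p = 0.14 with an estimated correlation; median 0.12 without EtOH 1). Of 19 members 0 passed over all genes and 3 rose over the list alone, with values of CLDN7 (0.48 ± 0.14), JUP (0.42 ± 0.11) and KRT80 (0.29 ± 0.08). In 3 other lists no member passed over all genes or over the list alone. Integrins and their partners rose (median 0.13, adjusted p = 0.00163, adjusted p = 0.082 with an estimated correlation), with values of PXN (0.38 ± 0.11) and ITGA2 (0.31 ± 0.11). Mitosis and G2/M genes fell (median -0.08, adjusted p = 0.0342, adjusted p = 0.649 with an estimated correlation), with 30 of 36 members below 0 and values of NDC80 (-0.31 ± 0.08) and HMMR (-0.26 ± 0.10). Ribosomal proteins rose (median 0.13, adjusted p = 0.000321, adjusted p = 0.649 with an estimated correlation; median 0.27 without EtOH 3), with values of RPL18 (0.20 ± 0.13) and RPS19 (0.16 ± 0.13) and bright-end signals of 9733 and 8858 in these arrays. Of the 55 genes past the threshold, 16 passed over all 12 contrasts together, and 1351 had an unadjusted p below 0.05. The count was 13 without C1OH-But3GalNAc 1, 24 without C1OH-But3GalNAc 2 (9 rose, and 11 were among the 55), 33 without C1OH-But3GlcNAc 1, 19 without EtOH 1, 32 without EtOH 2 and 25 without EtOH 3. CDC25A, DUSP5, EEF1A2, EHF, LAMB3 and THBD passed whichever array was left out. Calls ended in 8 or more of the 15 leave-one-out fits for DNAAF3, PLA2G2A (14), HLA-F-AS1 (13), AKR1C3, EREG, ID3, NQO1 (11) and EGR1 (10). List calls ended, with the medians given, without C1OH-But3GalNAc 1 (ribosomal 0.07, epithelial 0.04, matrix 0.08, integrins 0.09), without EtOH 1 (ribosomal 0.04), without EtOH 2 (ribosomal 0.07, epithelial 0.02), without either array of C1OH-Ac3ManNAc or either array of C1OH-But3ManNAc (epithelial 0.04), without C1OH-But3GalNAc 2 (epithelial 0.02, mitosis -0.02) and without EtOH 3 (epithelial 0.06, matrix 0.00, mitosis -0.03).

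C1OH-But3GlcNAc, the glucosamine scaffold with butyrate, raised 21 genes and lowered 35 at 40 µM. The most firmly raised were G0S2 at 1.72-fold (0.78 ± 0.08, adjusted p = 0.000656), LAMB3 at 1.63-fold (0.71 ± 0.07, adjusted p = 0.000656) and DUSP5 at 1.57-fold (0.65 ± 0.07, adjusted p = 0.000656). Lower were AQP3, a channel for water and glycerol, by 1.66-fold (-0.73 ± 0.08, adjusted p = 0.00151), OASL, an interferon-induced antiviral gene, by 1.64-fold (-0.71 ± 0.09, adjusted p = 0.00224), with signals of 278 ± 5.69 against 467 ± 41.8, and ID1 by 1.58-fold (-0.66 ± 0.10, adjusted p = 0.0113). Other rises were APCDD1L 1.71-fold, OTUB2 1.71-fold, AKR1C3 1.7-fold, SLC7A11 1.68-fold, TMEM132A 1.67-fold, ENPP4 1.55-fold and SPANXB1 1.53-fold. Other falls were CLEC3A 3.15-fold, C8orf82 1.78-fold, SUSD1 1.77-fold, PLAAT4 1.73-fold, C1orf53 1.7-fold, RCSD1 1.57-fold and CCDC3 1.54-fold, and the CLEC3A signal was 6.54 ± 0.656 against 57.00 ± 21.3, with the treated mean below every array's 40th percentile.

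Cholesterol biosynthesis fell with C1OH-But3GlcNAc (median -0.30, adjusted p = 3.36e-10, adjusted p = 0.0175 with an estimated correlation; median -0.18 without C1OH-But3GlcNAc 1). Among 19 members 4 fell over all genes and 11 fell over the list alone, including lanosterol synthase LSS (-0.53 ± 0.08), squalene epoxidase SQLE (-0.52 ± 0.09) and FDPS (-0.45 ± 0.09). Type I interferon response genes fell (median -0.19, adjusted p = 2.01e-06, adjusted p = 0.016 with an estimated correlation). Of 24 members 1 fell over all genes and 9 fell over the list alone, OASL among them, with values of IFIH1 (-0.67 ± 0.15), ISG15 (-0.59 ± 0.15) and IFIT3 (-0.54 ± 0.12). The NRF2 list rose (median 0.22, adjusted p = 4.17e-07, adjusted p = 0.0368 with an estimated correlation). Among 21 members 3 rose over all genes and 7 rose over the list alone, the former being AKR1C3 (0.77 ± 0.12), the cystine transporter SLC7A11 (0.75 ± 0.13) and NQO1 (0.58 ± 0.07). Immediate early genes rose (median 0.13, adjusted p = 9.28e-05, adjusted p = 0.0368 with an estimated correlation). Of 22 members 2 rose over all genes and 6 rose over the list alone, the former being DUSP5 (0.65 ± 0.07) and DUSP1 (0.51 ± 0.09). MHC class I and II genes fell (median -0.19, adjusted p = 7.62e-05, adjusted p = 0.218 with an estimated correlation; median -0.10 without EtOH 3). Among 19 members 0 passed over all genes and 5 fell over the list alone, with values of HLA-DRB1 (-0.87 ± 0.20), HLA-DPA1 (-0.78 ± 0.16) and HLA-DRA (-0.74 ± 0.17). Mesenchymal markers fell (median -0.11, adjusted p = 0.0238, adjusted p = 0.121 with an estimated correlation). Of 24 members 1 fell over all genes and 3 fell over the list alone, CDH11 (-0.54 ± 0.08) past the threshold and FN1 (-0.58 ± 0.13) not.

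The unfolded protein response and ATF4 list rose with C1OH-But3GlcNAc (median 0.09, adjusted p = 0.0469, adjusted p = 0.148 with an estimated correlation). Among 31 members 1 rose over all genes and 3 rose over the list alone, SLC7A11 among them and ERN1 with a value of 0.59 ± 0.15. The MYC list rose (median 0.09, adjusted p = 0.00806, adjusted p = 0.629 with an estimated correlation; median 0.15 without C1OH-But3GlcNAc 2 and 0.17 without EtOH 3). Of 24 members 0 passed over all genes and 2 rose over the list alone, with values of MYC (0.33 ± 0.09) and ODC1 (0.32 ± 0.09). No member passed either count in 3 more lists that rose: ribosomal proteins (median 0.13, adjusted p = 0.000768, adjusted p = 0.724 with an estimated correlation; median 0.27 without EtOH 3), with values of RPS3 (0.18 ± 0.14) and RPS25 (0.18 ± 0.13) and bright-end signals of 9432 and 9265 in these arrays, heat shock (median 0.10, adjusted p = 0.0412, adjusted p = 0.648 with an estimated correlation; median 0.17 without C1OH-But3GlcNAc 2 and 0.22 without EtOH 3), with values of HSPB8 (0.43 ± 0.12) and HSPE1 (0.25 ± 0.09), and the proteasome (median 0.10, adjusted p = 0.00406, adjusted p = 0.648 with an estimated correlation; median 0.18 without EtOH 3), with values of PSMB7 (0.28 ± 0.11) and PSMC4 (0.23 ± 0.09). Of the 56 genes past the threshold, 20 passed over all 12 contrasts together, and 1412 had an unadjusted p below 0.05. The count was 8 without C1OH-But3GlcNAc 1, 33 without C1OH-But3GlcNAc 2, 25 without EtOH 1 and 32 without EtOH 2. AQP3, DUSP5, G0S2, LAMB3 and OASL passed whichever array was left out. Calls ended in 8 or more of the 15 leave-one-out fits for RCSD1, TMEM132A (12), FDPS (11) and CLEC3A (8). Among the lists, calls ended, with these medians, without EtOH 1 (ribosomal 0.05, heat shock 0.03, MYC 0.06, proteasome 0.06, unfolded protein response 0.11), without EtOH 2 (ribosomal 0.07, heat shock 0.10, mesenchymal -0.11, MYC 0.08, proteasome 0.05, unfolded protein response 0.05), without C1OH-But3GlcNAc 1 (heat shock 0.10, mesenchymal -0.02, MYC 0.05, proteasome 0.06), without either array of C1OH-Ac3ManNAc or either array of C1OH-But3ManNAc (unfolded protein response 0.09), without C1OH-But3GlcNAc 2 (unfolded protein response 0.03) and without EtOH 3 (unfolded protein response 0.08).

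C1OH-But3ManNAc, the mannosamine scaffold with butyrate and a free C1 hydroxyl, raised 15 genes and lowered 10 at 30 µM. EGR1, an immediate early transcription factor, was higher by 1.8-fold (0.85 ± 0.15, adjusted p = 0.0362), AKR1C3 by 1.64-fold (0.71 ± 0.12, adjusted p = 0.0308), G0S2 by 1.59-fold (0.67 ± 0.08, adjusted p = 0.0099) and DUSP5 by 1.44-fold (0.53 ± 0.07, adjusted p = 0.0099). OASL was lower by 1.46-fold (-0.55 ± 0.09, adjusted p = 0.0301) and ATP5F1D, a subunit of mitochondrial ATP synthase, by 1.52-fold (-0.60 ± 0.10, adjusted p = 0.0308). Other rises were APCDD1L 1.74-fold, OTUB2 1.67-fold, UBE2H 1.59-fold, SPANXB1 1.59-fold, ZBTB21 1.56-fold and STEAP1 1.48-fold. Other falls were LOC284898 2.31-fold, PLEKHA7 1.67-fold, C8orf82 1.61-fold, COQ4 1.58-fold, IGFBP6 1.49-fold, BORCS7 1.48-fold, CAVIN3 1.42-fold and AQP3 1.39-fold.

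Immediate early genes rose with C1OH-But3ManNAc (median 0.13, adjusted p = 5.16e-05, adjusted p = 0.104 with an estimated correlation). Among 22 members 2 rose over all genes and 6 rose over the list alone, the former being EGR1 and DUSP5, while IER3 (0.37 ± 0.11) and DUSP1 (0.37 ± 0.09) did not pass over all genes. The NRF2 list rose (median 0.21, adjusted p = 2.11e-05, adjusted p = 0.104 with an estimated correlation). Of 21 members 2 rose over all genes and 7 rose and 1 fell over the list alone, the former being AKR1C3 (0.71 ± 0.12) and NQO1 (0.43 ± 0.07), with a value of 0.40 ± 0.11 for GCLM, a subunit of the enzyme that starts glutathione synthesis. Cholesterol biosynthesis fell (median -0.23, adjusted p = 2.17e-05, adjusted p = 0.104 with an estimated correlation). Among 19 members 0 passed over all genes and 1 rose and 6 fell over the list alone, with values of EBP (-0.50 ± 0.14), FDPS (-0.42 ± 0.09) and HMGCS1 (-0.34 ± 0.13). Interferon response genes fell (median -0.14, adjusted p = 0.0273, adjusted p = 0.105 with an estimated correlation). Of 24 members 1 fell over all genes and 1 fell over the list alone, OASL in both counts and IFIH1 with a value of -0.34 ± 0.15. Glycolysis and hypoxia genes rose (median 0.07, adjusted p = 0.0384, adjusted p = 0.586 with an estimated correlation). Among 32 members 0 passed over all genes and 1 rose over the list alone, with values of VEGFA (0.43 ± 0.10) and LDHA (0.19 ± 0.14). NF-kB targets rose (median 0.19, adjusted p = 0.00067, adjusted p = 0.105 with an estimated correlation). Of 23 members 0 passed either count, with values of LIF (0.38 ± 0.12) and IL6 (0.32 ± 0.10).

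Ribosomal proteins rose with C1OH-But3ManNAc (median 0.19, adjusted p = 2.66e-07, adjusted p = 0.607 with an estimated correlation; median 0.34 without C1OH-But3ManNAc 2, 0.11 without EtOH 1 and 0.34 without EtOH 3). Among 34 members 0 passed either count, with values of RPS24 (0.28 ± 0.12) and RPS3 (0.26 ± 0.14). The bright-end signals of these arrays were 10821 and 9195, their 28S signals 657 and 446, and with that measure as a covariate the ribosomal median was -0.04. Of the 25 genes past the threshold, 8 passed over all 12 contrasts together, and 1462 had an unadjusted p below 0.05. The count was 0 without C1OH-But3ManNAc 1 or EtOH 1, 4 without C1OH-But3ManNAc 2, 7 without EtOH 2 and 2 without EtOH 3. It was 2 with array weights and 1 with the replicate block. Calls ended in 8 or more of the 15 leave-one-out fits for AQP3 (13), CAVIN3 (12), PLEKHA7, SPANXB1 (11) and EGR1, ZBTB21 (9). Calls of lists ended, with the medians given, without C1OH-But3ManNAc 1 (ribosomal 0.06, glycolysis 0.04, interferon -0.13), without either array of C1OH-But3GlcNAc (glycolysis 0.07), without EtOH 1 (glycolysis 0.05, interferon -0.12), without EtOH 2 (glycolysis 0.05) and without C1OH-But3ManNAc 2 (interferon -0.09).

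C6OH-But3ManNAc, the same scaffold with the free hydroxyl at C6, raised 2 genes and lowered 0 at 30 µM by limma. These were EHF at 1.71-fold (0.77 ± 0.11, adjusted p = 0.0383) and EEF1A2 at 1.56-fold (0.64 ± 0.09, adjusted p = 0.0383), with EHF signals of 347 ± 37.1 against 196 ± 3.47. Extracellular matrix genes rose (median 0.17, adjusted p = 1.73e-07, adjusted p = 0.0768 with an estimated correlation). Of 32 members 0 passed over all genes and 2 rose over the list alone, with a value of 0.35 ± 0.08 for LOX, which crosslinks collagen, and of 0.49 ± 0.21 for THBS2. NF-kB targets rose (median 0.11, adjusted p = 3.64e-05, adjusted p = 0.0768 with an estimated correlation; median 0.19 without C6OH-But3ManNAc 1 and 0.18 without EtOH 2). Among 23 members 0 passed over all genes and 5 rose over the list alone, with values of IL6 (0.45 ± 0.10), ICAM1 (0.42 ± 0.10) and TNFAIP2 (0.42 ± 0.09). No member passed either count in 4 further lists that rose: chemokines and their receptors (median 0.11, adjusted p = 0.027, adjusted p = 0.188 with an estimated correlation; median 0.18 without EtOH 2), with values of CXCL2 (0.41 ± 0.14) and CXCL8 (0.35 ± 0.13), glycolysis and hypoxia (median 0.06, adjusted p = 0.0267, adjusted p = 0.376 with an estimated correlation; median 0.09 without C6OH-But3ManNAc 1), with VEGFA (0.31 ± 0.10) and PFKFB4 (0.28 ± 0.12), integrins (median 0.10, adjusted p = 0.0388, adjusted p = 0.188 with an estimated correlation), with PXN (0.32 ± 0.11) and ITGA3 (0.16 ± 0.08), and the TGF-beta response (median 0.09, adjusted p = 0.0249, adjusted p = 0.188 with an estimated correlation), with TGFBI (0.27 ± 0.08) and CCN2 (0.24 ± 0.10). The cholesterol list had a median of -0.10 (adjusted p = 0.0997) and the NRF2 list of -0.09 (adjusted p = 0.148). Unadjusted p lay below 0.05 for 835 genes, against 710.35 expected by chance. Both genes also passed over all 12 contrasts together, and the count was 1 without Ac4ManNLev 1, Ac4ManNLev 2 or EtOH 3 and 0 without each of the other 12 arrays. Lists were no longer called, with these medians, without C6OH-But3ManNAc 2 (chemokines 0.11, glycolysis 0.03, integrins 0.07), without EtOH 3 (chemokines 0.06, integrins 0.08, TGF-beta 0.06), without EtOH 1 (glycolysis 0.03, integrins 0.10, TGF-beta 0.07), without EtOH 2 (glycolysis 0.03) and without C6OH-But3ManNAc 1 (TGF-beta 0.08).

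**Figure D1:**
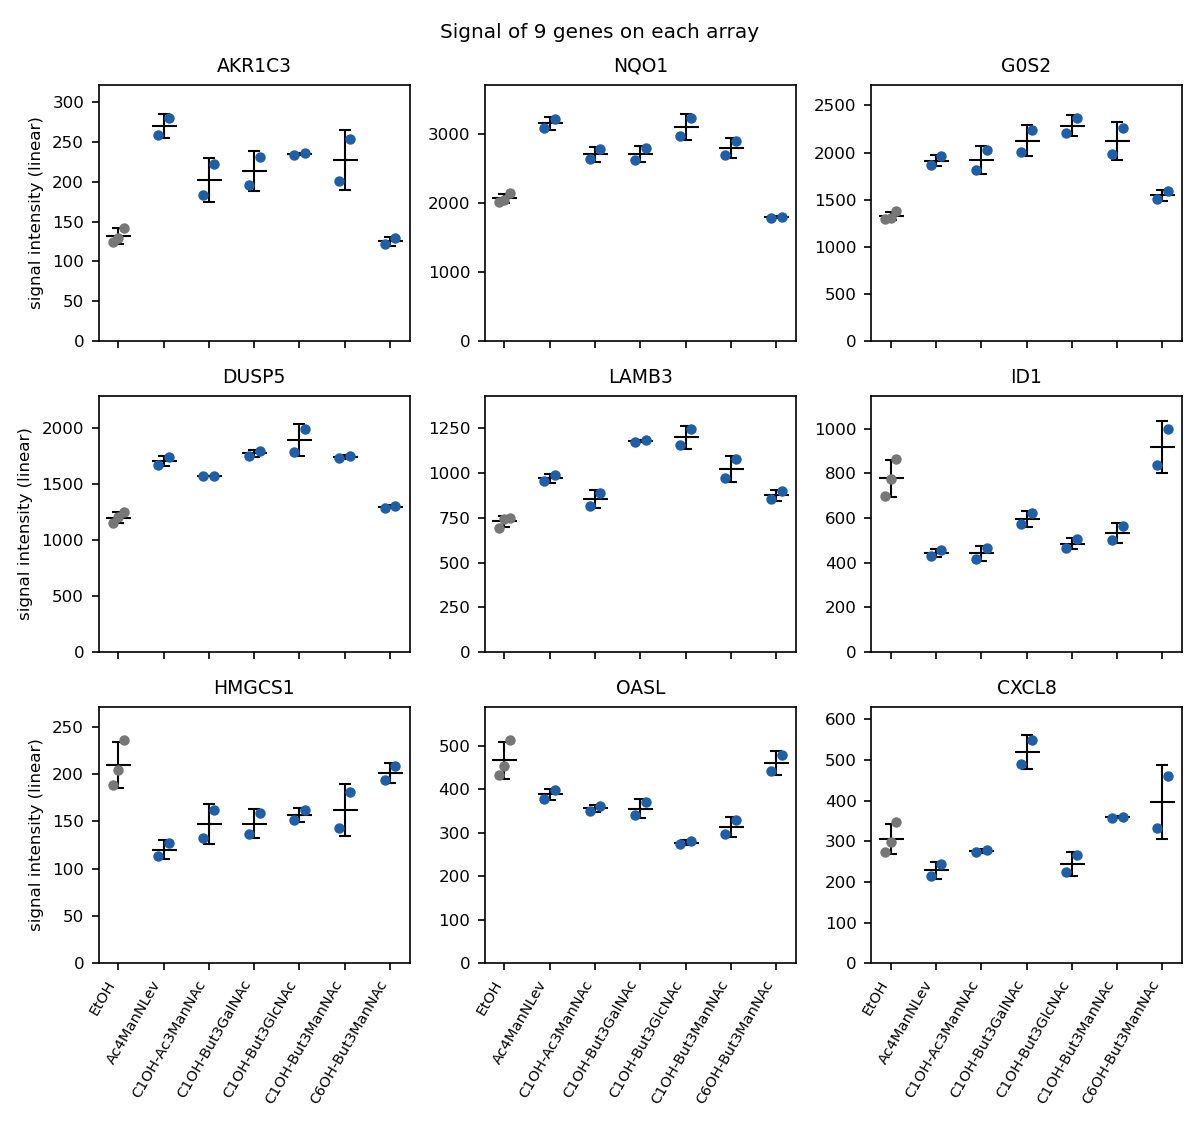
Signal per array on a linear intensity scale (points, with mean and SD bars) of 9 genes in the vehicle (grey, 3 arrays) and the 6 analogs (blue, 2 arrays each). NQO1 lies at 3151 with Ac4ManNLev against 2064 with vehicle, and CXCL8 at 519.7 with C1OH-But3GalNAc against 306 with vehicle.

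Genes followed whatever their values did not pass in any of the 6 vehicle contrasts. The cell cycle inhibitor CDKN1A, a known target of histone deacetylase inhibitors, had log2 changes of 0.08 to 0.28, the highest with C1OH-But3GalNAc (0.28 ± 0.10, adjusted p = 0.328). MUC1 ranged from -0.57 to 0.06, the lowest with Ac4ManNLev (-0.57 ± 0.23, adjusted p = 0.434), CXCR4 from -0.33 to 0.02 and the gelatinase MMP9 from -0.37 to 0.05. Cyclin D1 (CCND1) ranged from -0.22 to 0.09, survivin (BIRC5) from -0.22 to -0.05, RELA from -0.10 to 0.12 and GNE, the enzyme that starts sialic acid synthesis, from -0.16 to -0.01. The 95% intervals of CDKN1A ran from -0.14 to 0.50 over the 6 contrasts.

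Growth and apoptosis are named in the series design, and 19 of the 41 lists, most of those on these themes among them, passed camera in no vehicle contrast. Pro-apoptotic genes had medians of -0.05 to 0.03, adjusted p ≥ 0.478, anti-apoptotic genes of -0.04 to 0.05, adjusted p ≥ 0.28, p53 targets of 0.02 to 0.13, adjusted p ≥ 0.0894 and DNA replication genes of -0.07 to 0.01, adjusted p ≥ 0.0621. Genes that histone deacetylase inhibitors induce had medians of 0.02 to 0.08, adjusted p ≥ 0.087, histone deacetylases and acetyltransferases of -0.08 to -0.03, adjusted p ≥ 0.29, and histones of -0.14 to 0.16, adjusted p ≥ 0.0559. Sialic acid metabolism ran from -0.09 to 0.04, adjusted p ≥ 0.407, the hexosamine pathway from -0.02 to 0.06, adjusted p ≥ 0.0894 and O- and N-glycan enzymes from -0.01 to 0.04, adjusted p ≥ 0.101. For fatty acid oxidation the range was -0.03 to 0.03, adjusted p ≥ 0.478, for lysosomal genes -0.05 to 0.06, adjusted p ≥ 0.087, for metalloproteinases -0.04 to 0.10, adjusted p ≥ 0.0572, for metallothioneins -0.16 to 0.14, adjusted p ≥ 0.204 and for neuronal and cytoskeletal genes -0.05 to 0.03, adjusted p ≥ 0.28. Markers of other cell types passed in none: leukocyte (-0.07 to 0.06, adjusted p ≥ 0.393), erythroid (-0.26 to -0.07, adjusted p ≥ 0.101), endothelial (-0.07 to 0.11, adjusted p ≥ 0.739) and luminal breast (-0.16 to 0.00, adjusted p ≥ 0.269). Adjusted over the list alone, members passed 18 times over the 6 contrasts for histone deacetylase inhibitor genes, 13 for p53 targets, 11 for pro-apoptotic genes, 10 for endothelial markers (in both directions), 9 for metalloproteinases and at most 5 for each other list. In these 19 lists single members did pass over all genes, and 2 of these genes were picked after their values were seen: RHOB of the histone deacetylase inhibitor list rose with 3 analogs and CCNG1 of the p53 list fell with 1. CASP10 of the pro-apoptotic list and ADAM12 of the metalloproteinase list each fell with 1.

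**Figure D2:**
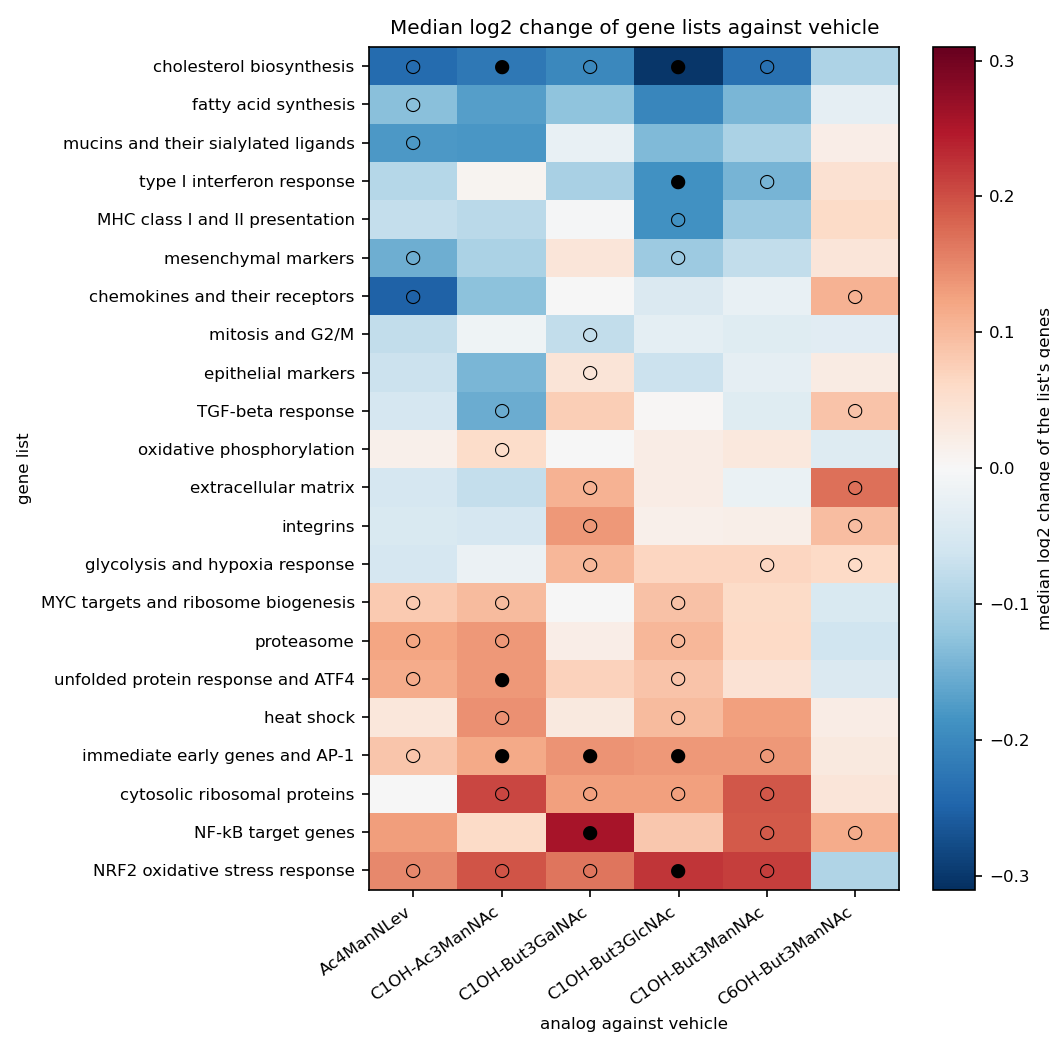
Median log2 change against vehicle (colour) of the 22 lists called in at least 1 vehicle contrast, for the 6 analogs; an open circle marks a camera call and a filled circle one that also passed with an estimated correlation. Cholesterol biosynthesis lies between -0.30 and -0.10 and is called with 5 analogs.

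Shared responses were counted over the 6 vehicle contrasts, in which 112 genes passed at least once. Of these, 32 passed with 2 or more analogs in the same direction, 22 rising and 10 falling, and 0 passed in opposite directions by limma. G0S2 and SPANXB1 rose with 5 analogs, and AKR1C3, DUSP5, LAMB3 and NQO1 with 4, while ID1, AQP3, CAVIN3 and MATN2 fell with 3. C1OH-But3GalNAc and C1OH-But3GlcNAc shared 18 genes, C1OH-But3GlcNAc and C1OH-But3ManNAc 15, C1OH-But3GalNAc and C1OH-But3ManNAc 14, and Ac4ManNLev and C1OH-But3GlcNAc 14. These 4 pairs shared at most 9, 7, 6 and 7 genes, and 2 or more analogs at most 23 (mean 15.46), in 50 simulations of unchanged groups on shared vehicle arrays. Each took as many genes of smallest p as had passed, a choice made after the overlap was seen. Independent lists would share at most 0.0971. Across genes, which are not independent replicates, log2 changes of analog pairs correlated with r from 0.33 to 0.55 (simulated 0.40). Covariances exceeded simulated ones by 0.000179 to 0.0125. The 3 vehicle arrays cannot form 2 sets of 2, so part of the overlap can come from the shared control. The 32 genes became 21 without Ac4ManNLev 2, 18 without C1OH-But3GlcNAc 1, 13 without EtOH 1, 20 without EtOH 2 and 18 without EtOH 3.

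The C1OH and C6OH forms of But3ManNAc, both at 30 µM, differ in which hydroxyl is free, and this is the single pair at a matched dose. NQO1 was higher with the C1OH form by 1.55-fold (0.63 ± 0.08, adjusted p = 0.0178) (95% interval 0.46 to 0.81), with signals of 2793 ± 149 against 1792 ± 13.05 (SD, 2 arrays each). ID1 was lower with the C1OH form by 1.69-fold (-0.76 ± 0.11, adjusted p = 0.0482) (95% interval -1.0 to -0.52), with signals of 534 ± 45.5 against 918 ± 115. The NRF2 list was higher with C1OH (median 0.25, adjusted p = 1.05e-08, adjusted p = 0.0366 with an estimated correlation; median 0.15 without C1OH-But3ManNAc 1). Of 21 members 1 rose over all genes and 5 rose over the list alone, with values of AKR1C3 (0.78 ± 0.13), SLC7A11 (0.53 ± 0.14) and GCLM (0.50 ± 0.12) beside NQO1. The interferon list was lower (median -0.18, adjusted p = 7.24e-06, adjusted p = 0.0197 with an estimated correlation). Among 24 members 0 passed over all genes and 2 fell over the list alone, with values of OASL (-0.53 ± 0.09) and IFIT2 (-0.41 ± 0.11).

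In the C1OH form compared with the C6OH form, TGF-beta response genes were lower (median -0.10, adjusted p = 0.00145, adjusted p = 0.0846 with an estimated correlation; median -0.17 without C1OH-But3ManNAc 2 and -0.15 without C6OH-But3ManNAc 1). Of 23 members 1 fell over all genes and 3 fell over the list alone, ID1 among them and ID3 with a value of -1.17 ± 0.30. Extracellular matrix genes were lower (median -0.18, adjusted p = 2.31e-05, adjusted p = 0.0846 with an estimated correlation). Among 32 members 0 passed over all genes and 3 fell over the list alone, with values of LOXL4 (-0.41 ± 0.08) and FN1 (-0.40 ± 0.14). Epithelial markers were lower (median -0.05, adjusted p = 0.03, adjusted p = 0.116 with an estimated correlation). Of 19 members 0 passed over all genes and 1 fell over the list alone, with values of PKP3 (-0.49 ± 0.12) and KRT7 (-0.34 ± 0.11). Of the 19 cholesterol genes, lower with C1OH (median -0.11, adjusted p = 0.00566, adjusted p = 0.192 with an estimated correlation), 0 passed either count, with values of EBP (-0.40 ± 0.16) and INSIG1 (-0.30 ± 0.11). Mesenchymal markers were lower (median -0.10, adjusted p = 0.00566, adjusted p = 0.0846 with an estimated correlation). Among 24 members 0 passed over all genes and 2 fell over the list alone, with values of CDH11 (-0.40 ± 0.09) and TAGLN (-0.50 ± 0.19). MHC genes were lower (median -0.16, adjusted p = 0.000421, adjusted p = 0.23 with an estimated correlation). Of 19 members 0 passed either count, with values of HLA-DRB1 (-0.66 ± 0.22) and HLA-F (-0.33 ± 0.10).

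Higher in the C1OH than in the C6OH form were immediate early genes (median 0.09, adjusted p = 0.00435, adjusted p = 0.0876 with an estimated correlation; median 0.14 without C1OH-But3ManNAc 2), where of 22 members 0 passed over all genes and 1 rose over the list alone, with values of DUSP5 (0.42 ± 0.07) and EGR1 (0.47 ± 0.16). The unfolded protein response list was higher (median 0.09, adjusted p = 0.0165, adjusted p = 0.0846 with an estimated correlation). Among 31 members 0 passed over all genes and 2 rose over the list alone, with values of CHAC1 (0.60 ± 0.27) and SDF2L1 (0.41 ± 0.11). The MYC list was higher (median 0.13, adjusted p = 0.00224, adjusted p = 0.329 with an estimated correlation; median 0.20 without C1OH-But3ManNAc 2). Of 24 members 0 passed either count, with values of RRP12 (0.31 ± 0.17) and MYC (0.20 ± 0.09). Proteasome genes were higher (median 0.12, adjusted p = 0.000231, adjusted p = 0.603 with an estimated correlation). Among 25 members 0 passed either count, with values of PSMB7 (0.25 ± 0.12) and PSMA5 (0.22 ± 0.10). Ribosomal proteins were higher (median 0.16, adjusted p = 1e-05, adjusted p = 0.694 with an estimated correlation; median 0.29 without C1OH-But3ManNAc 2 and 0.10 without C6OH-But3ManNAc 1). Of 34 members 0 passed either count, with values of RPS24 (0.27 ± 0.13) and RPL22 (0.25 ± 0.14), while bright-end signals were 10821 and 9195 against 8489 and 9211 and the median with that covariate was -0.02. Unadjusted p lay below 0.05 for 799 genes, and both genes passed over all 12 contrasts together. The NQO1 call ended without C1OH-But3ManNAc 1, C6OH-But3ManNAc 1 or C6OH-But3ManNAc 2, and the ID1 call with any of 13 of the 15 arrays left out, all but EtOH 1 and EtOH 3. Without C1OH-But3ManNAc 2 the count was 4, with NQO1 but not ID1 among them. Lists were no longer called, with the medians given, without C1OH-But3ManNAc 2 (cholesterol -0.08, epithelial -0.15, mesenchymal -0.06), without C6OH-But3ManNAc 2 (cholesterol -0.06, epithelial -0.11, unfolded protein response 0.01), without C1OH-But3ManNAc 1 (ribosomal 0.02, epithelial -0.12, immediate early 0.04, MYC 0.06, proteasome 0.07, unfolded protein response 0.04) and without C6OH-But3ManNAc 1 (epithelial -0.06, mesenchymal -0.07).

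**Figure D3:**
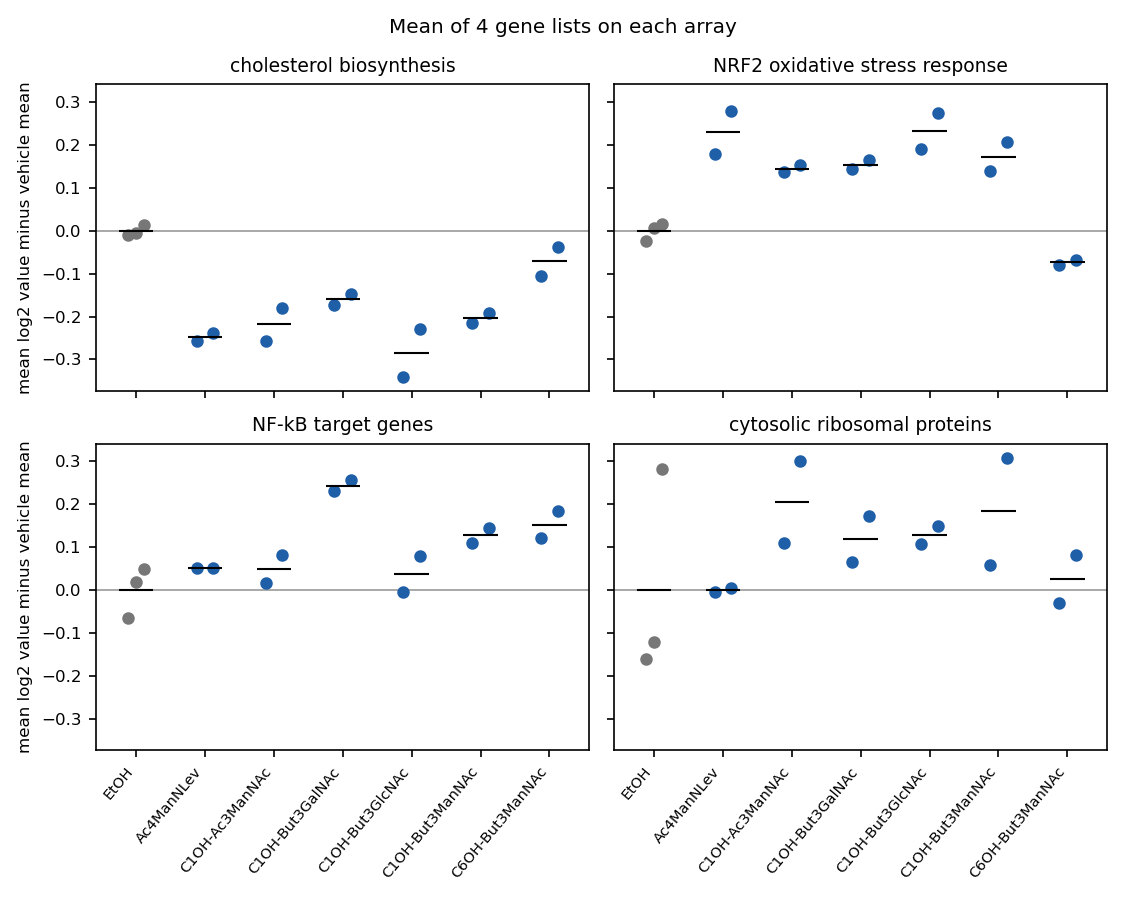
Mean log2 value of 4 gene lists per array, minus the vehicle mean (points, with a line at each group mean), in the vehicle and the 6 analogs. The cholesterol list lies between -0.34 and -0.04 in the analog arrays and between -0.01 and 0.01 in the vehicle arrays, while the ribosomal list spans -0.16 to 0.28 within the vehicle.

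Butyrate and acetate on the C1OH mannosamine scaffold were compared at unequal doses, 30 µM C1OH-But3ManNAc against 100 µM C1OH-Ac3ManNAc. No gene passed by limma, and 861 had an unadjusted p below 0.05. The genes with the smallest p were PSMB10, an immunoproteasome subunit (-0.78 ± 0.13, adjusted p = 0.197, 95% interval -1.07 to -0.50), SSNA1 (-0.67 ± 0.11, adjusted p = 0.197, 95% interval -0.91 to -0.43) and CASC15 (1.84 ± 0.32, adjusted p = 0.197, 95% interval 1.16 to 2.52). Of the 41 lists 0 passed. Without C1OH-Ac3ManNAc 1 the count was 1.

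The acetylated pair, 75 µM Ac4ManNLev against 100 µM C1OH-Ac3ManNAc, differ in the N-acyl group and at C1. No gene passed by limma, and 611 had an unadjusted p below 0.05, below the 710.35 expected by chance. The smallest p belonged to LANCL2 (-0.47 ± 0.08, adjusted p = 0.716, 95% interval -0.65 to -0.29), the adenylate kinase AK4 (-0.50 ± 0.09, adjusted p = 0.716, 95% interval -0.70 to -0.30) and STT3A, an oligosaccharyltransferase subunit (0.61 ± 0.12, adjusted p = 0.997, 95% interval 0.34 to 0.88). Ribosomal proteins were lower with Ac4ManNLev (median -0.21, adjusted p = 1.49e-09, adjusted p = 0.928 with an estimated correlation). Among 34 members 0 passed either count, with values of RPS7 (-0.33 ± 0.15) and RPL32 (-0.29 ± 0.18), while bright-end signals were 8414 and 8635 against 9433 and 10370.1 and the median with that covariate was 0.02. Without C1OH-Ac3ManNAc 1 the count of genes was 1. The list call ended, with this median, without C1OH-Ac3ManNAc 2 (ribosomal -0.12).

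Mannosamine and glucosamine scaffolds with butyrate were compared at 30 µM C1OH-But3ManNAc and 40 µM C1OH-But3GlcNAc. No gene passed by limma, and 820 had an unadjusted p below 0.05. The smallest p belonged to KHDRBS2 (-1.33 ± 0.26, adjusted p = 0.827, 95% interval -1.89 to -0.77), the peroxisomal import receptor PEX5 (-0.71 ± 0.14, adjusted p = 0.827, 95% interval -1.02 to -0.41) and ZNF446 (-1.91 ± 0.39, adjusted p = 0.827, 95% interval -2.75 to -1.06). Cholesterol genes were higher with the mannosamine form (median 0.11, adjusted p = 0.0461, adjusted p = 0.679 with an estimated correlation). Of 19 members 0 passed either count, with values of LSS (0.27 ± 0.08) and SQLE (0.27 ± 0.09). Interferon genes were higher as well (median 0.09, adjusted p = 0.0403, adjusted p = 0.264 with an estimated correlation). Among 24 members 0 passed either count, with values of ISG15 (0.40 ± 0.16) and IFITM1 (0.27 ± 0.09). Both calls depended on single arrays and ended, with these medians, without either array of Ac4ManNLev (cholesterol 0.11), without C1OH-But3GlcNAc 1 (cholesterol 0.06, interferon 0.11), without C1OH-But3ManNAc 2 (cholesterol 0.08, interferon 0.03), without EtOH 2 (cholesterol 0.11, interferon 0.09) and without C1OH-But3GlcNAc 2 (interferon 0.09).

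Against 50 µM C1OH-But3GalNAc, 30 µM C1OH-But3ManNAc gave no gene past the threshold by limma, with 618 at an unadjusted p below 0.05. The smallest p belonged to the melanosomal transporter SLC45A2 (1.28 ± 0.22, adjusted p = 0.275, 95% interval 0.81 to 1.74), CASC15 (1.77 ± 0.32, adjusted p = 0.275, 95% interval 1.09 to 2.45) and the tumour suppressor NF2 (1.36 ± 0.25, adjusted p = 0.275, 95% interval 0.83 to 1.89). Epithelial markers were lower with the mannosamine form (median -0.19, adjusted p = 0.000389, adjusted p = 0.0547 with an estimated correlation). Of 19 members 0 passed over all genes and 2 fell over the list alone, with values of PKP3 (-0.43 ± 0.12) and KRT7 (-0.41 ± 0.11). NF-kB targets were lower (median -0.10, adjusted p = 0.00929, adjusted p = 0.267 with an estimated correlation; median -0.18 without C1OH-But3GalNAc 2). Among 23 members 0 passed either count, with values of CXCL8 (-0.51 ± 0.14), TNFAIP2 (-0.33 ± 0.10) and ICAM1 (-0.31 ± 0.11). Also lower were extracellular matrix genes (median -0.11, adjusted p = 0.00929, adjusted p = 0.267 with an estimated correlation), where of 32 members 0 passed either count and values were LAMA5 (-0.40 ± 0.12) and FBN1 (-0.26 ± 0.10). Glycolysis and hypoxia genes were lower (median -0.06, adjusted p = 0.0175, adjusted p = 0.406 with an estimated correlation; median -0.10 without C1OH-But3ManNAc 1), where of 32 members 0 passed over all genes and 1 fell over the list alone and values were PFKFB4 (-0.59 ± 0.13) and NDRG1 (-0.29 ± 0.08). Lysosomal genes were lower (median -0.11, adjusted p = 0.00929, adjusted p = 0.267 with an estimated correlation), where of 29 members 0 passed either count and values were MANBA (-0.35 ± 0.17) and MAN2B1 (-0.24 ± 0.15). The MHC list was lower (median -0.11, adjusted p = 0.0124, adjusted p = 0.45 with an estimated correlation; median -0.18 without C1OH-But3GalNAc 1), where of 19 members 0 passed either count and values were HLA-DRB1 (-0.42 ± 0.22) and HLA-DMA (-0.22 ± 0.12). The TGF-beta list was lower (median -0.08, adjusted p = 0.0115, adjusted p = 0.267 with an estimated correlation; median -0.15 without C1OH-But3GalNAc 2), where of 23 members 0 passed either count and values were LTBP3 (-0.40 ± 0.16) and SMAD7 (-0.36 ± 0.15). Without C1OH-But3GalNAc 2 the count of genes was 6, and without C1OH-But3ManNAc 2 it was 1. Calls among the lists ended, with these medians, without C1OH-But3GalNAc 1 (matrix -0.08, glycolysis -0.08, lysosome -0.09, NF-kB -0.06, TGF-beta -0.06), without C1OH-But3ManNAc 2 (matrix -0.11, glycolysis -0.06, lysosome -0.10, MHC -0.14, NF-kB -0.13, TGF-beta -0.12), without C1OH-But3GalNAc 2 (glycolysis -0.05, MHC -0.07) and without C1OH-But3ManNAc 1 (TGF-beta -0.10).

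C1OH-But3GlcNAc at 40 µM and C1OH-But3GalNAc at 50 µM differed in the chemokine CXCL8, which was lower with the glucosamine form by 2.06-fold (-1.04 ± 0.14, adjusted p = 0.0488) (95% interval -1.35 to -0.73), with signals of 245 ± 29.6 against 519.7 ± 41.8. NF-kB targets were lower (median -0.15, adjusted p = 2.89e-06, adjusted p = 0.0439 with an estimated correlation; median -0.23 without C1OH-But3GalNAc 2). Of 23 members 1 fell over all genes and 4 fell over the list alone, CXCL8 among them and TNFAIP2 (-0.49 ± 0.10) and IL1B (-0.52 ± 0.19) as further values. The interferon list was lower (median -0.13, adjusted p = 0.000128, adjusted p = 0.0439 with an estimated correlation). Among 24 members 0 passed over all genes and 3 fell over the list alone, with values of IFI27 (-0.40 ± 0.07) and ISG15 (-0.45 ± 0.16). MHC genes were lower (median -0.22, adjusted p = 2.89e-06, adjusted p = 0.122 with an estimated correlation), where of 19 members 0 passed over all genes and 1 fell over the list alone and values were HLA-DMA (-0.51 ± 0.12) and HLA-DRB1 (-0.70 ± 0.22). Epithelial markers were lower (median -0.10, adjusted p = 0.00181, adjusted p = 0.053 with an estimated correlation; median -0.17 without C1OH-But3GalNAc 1, -0.06 without C1OH-But3GalNAc 2 and -0.07 without C1OH-But3GlcNAc 1), where of 19 members 0 passed over all genes and 2 fell over the list alone and values were JUP (-0.56 ± 0.12) and KRT7 (-0.42 ± 0.11). Extracellular matrix genes were lower (median -0.10, adjusted p = 0.00629, adjusted p = 0.191 with an estimated correlation), where of 32 members 0 passed over all genes and 4 fell over the list alone and values were FN1 (-0.57 ± 0.14) and LOXL4 (-0.43 ± 0.08). Cholesterol genes were lower (median -0.10, adjusted p = 0.00615, adjusted p = 0.174 with an estimated correlation; median -0.16 without C1OH-But3GlcNAc 2), where of 19 members 0 passed either count and values were SQLE (-0.24 ± 0.09) and LSS (-0.24 ± 0.08).

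Also lower with C1OH-But3GlcNAc than with C1OH-But3GalNAc were glycolysis and hypoxia genes (median -0.07, adjusted p = 0.00104, adjusted p = 0.174 with an estimated correlation), where of 32 members 0 passed over all genes and 1 fell over the list alone and values were PFKFB4 (-0.57 ± 0.13) and SLC2A3 (-0.22 ± 0.09). Integrins were lower (median -0.11, adjusted p = 0.00615, adjusted p = 0.0823 with an estimated correlation), where of 21 members 0 passed either count and values were ITGA1 (-0.53 ± 0.23) and ITGB4 (-0.34 ± 0.15). Lysosomal genes were lower (median -0.11, adjusted p = 0.00629, adjusted p = 0.191 with an estimated correlation), where of 29 members 0 passed either count and values were GM2A (-0.24 ± 0.09) and TPP1 (-0.22 ± 0.09). Mesenchymal markers were lower (median -0.07, adjusted p = 0.00673, adjusted p = 0.0823 with an estimated correlation; median -0.12 without C1OH-But3GalNAc 1), where of 24 members 0 passed over all genes and 1 fell over the list alone and values were FN1 (-0.57 ± 0.14) and CDH11 (-0.26 ± 0.09). The TGF-beta list was lower (median -0.09, adjusted p = 0.0184, adjusted p = 0.174 with an estimated correlation), where of 23 members 0 passed either count and values were PMEPA1 (-0.29 ± 0.11) and LTBP2 (-0.43 ± 0.17). The MYC list was higher (median 0.09, adjusted p = 0.00952, adjusted p = 0.435 with an estimated correlation; median 0.16 without C1OH-But3GlcNAc 2), where of 24 members 0 passed either count and values were PA2G4 (0.40 ± 0.13) and POLR1B (0.26 ± 0.10). Unadjusted p lay below 0.05 for 922 genes, and CXCL8 passed over all 12 contrasts together. The CXCL8 call ended with any of 12 of the 15 arrays left out, all but EtOH 1, C6OH-But3ManNAc 1 and C6OH-But3ManNAc 2. Without C1OH-But3GalNAc 2 there were 6 other genes past the threshold and without C1OH-But3GalNAc 1 there was 1, all higher with C1OH-But3GlcNAc. Of the settings with all arrays, the call held with a pseudocount of 64 and the 60th percentile filter and ended under the other 8. Calls among the lists ended, with the medians given, without C1OH-But3GalNAc 2 (cholesterol -0.07, MYC 0.07), without C1OH-But3GlcNAc 1 (cholesterol -0.04, integrins -0.10, mesenchymal -0.11, MYC 0.03, TGF-beta -0.19), without C1OH-But3GalNAc 1 (matrix -0.08, integrins -0.09, TGF-beta -0.07) and without C1OH-But3GlcNAc 2 (lysosome -0.07).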

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

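The tests of the cholesterol list and of the shared vehicle arrays were chosen after their results were seen. The tests of the ribosomal list were written down first, although the list's rise and the brightness of the arrays had been seen.

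Probe sets without a single gene symbol entered no comparison of genes, and some carried a signal: of 6135 tested by limma against vehicle, 8 passed with Ac4ManNLev, 4 with C1OH-Ac3ManNAc, 5 with C1OH-But3GalNAc, 6 with C1OH-But3GlcNAc, 1 with C1OH-But3ManNAc and 1 with C6OH-But3ManNAc. A control probe set for the middle of the 28S ribosomal RNA, outside the gene comparisons, had a signal of 657 in C1OH-But3ManNAc 1 and 603 in C1OH-Ac3ManNAc 1, against 365 to 392 in the vehicle arrays, and 9 of 12 analog arrays lay above the highest vehicle array.

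The cholesterol biosynthesis list was lower with 5 of 6 analogs at the preset correlation, and 3 of these calls did not pass with an estimated one (adjusted p = 0.0607 with Ac4ManNLev, adjusted p = 0.0821 with C1OH-But3GalNAc and adjusted p = 0.104 with C1OH-But3ManNAc). At the preset correlation a single odd vehicle array is argued against: over 5 contrasts and 3 vehicle arrays left out, the 15 medians ran from -0.33 to -0.15 with a highest adjusted p of 0.000706. The brightness of the arrays as the whole cause is argued against too, since with it as a covariate the 5 medians ran from -0.31 to -0.16 with a highest adjusted p of 0.000112. Lower expression of sterol synthesis genes with C1OH-Ac3ManNAc and C1OH-But3GlcNAc, whose calls passed both ways, is a hypothesis found and tested on the same data. The latter's median of -0.30 was -0.18 without C1OH-But3GlcNAc 1. Ethanol in the analog cultures and cell density stay open, as neither is given. The series design speaks of relatively toxic analogs at an inhibitory dose, and which ones is unclear.

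The ribosomal protein list was higher with 4 analogs at the preset correlation, and none of these calls passed with an estimated one (adjusted p = 0.466 to 0.724). Within groups its mean followed that of the 200 brightest other genes over the 15 arrays (Pearson r = 0.99, exact permutation p = 0.00521 over 384 permutations; Spearman rho = 0.97, exact permutation p = 0.0104), and r was 0.98 without EtOH 3 and C1OH-But3ManNAc 1, so variation between arrays at the bright end is a candidate explanation. The list's median lay above the 95% range of 1000 sets of equally bright genes in 3 of the 4 contrasts (0.21, 0.13 and 0.13 against matched medians of 0.17, 0.10 and 0.08, and 0.19 against 0.18 in the other). That range covers the choice of genes and leaves out the spread between arrays, so a shift shared by all bright genes and one of the ribosomal genes cannot be told apart. A biological response of ribosomal genes stays open.

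Several genes were shared by the analogs, which are all read against the same vehicle arrays. Genes that fell with C1OH-But3GlcNAc or C1OH-But3GalNAc had a median difference of -0.26 between C1OH-But3ManNAc and C6OH-But3ManNAc (42 of 48 below 0, p = 0.000112 with an estimated correlation by limma's camera), a contrast that uses none of the arrays that chose them. Genes that rose had a median difference of 0.13 (32 of 45 above 0, p = 0.00318 with an estimated correlation). The difference between the But3ManNAc forms argues against the shared vehicle arrays as the whole cause. Whether the response belongs to butyrate, to the free hydroxyl, to toxicity or to several analogs alike stays open.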

How the results depend on the processing

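The bright-end covariate (log2 of the signal that the brightest 0.1% of an array's probe sets exceed) was chosen after seeing the data; all other alternatives were planned. No gene past the threshold reversed under any setting, and of 1620 leave-one-out values of 108 named calls 1018 stayed past the threshold and 602 did not. Of these 108 calls 75 ended with no intensity trend, 61 with the replicate block, 43 with no filter, 37 with the mean of probe sets, 35 with the bright-end covariate, 22 with array weights and at most 5 under each other setting, with 7 not tested under the 60th percentile filter. The replicate numbers do not pair the samples: over 42 pairs with the same number r ran from -0.15 to 0.13, and 8 of 15 arrays were closest to an array of their own number. With the replicate block, in which EtOH 3 has no partner and drops out, C1OH-But3GalNAc had 19 genes past the threshold against vehicle, C1OH-But3ManNAc 1, C6OH-But3ManNAc 1, C1OH-But3ManNAc against C6OH-But3ManNAc 1, C1OH-But3GlcNAc against C1OH-But3GalNAc 0, and the overlap between analogs was 19. Counts that differ by over 1.5 times from those reported follow, and their cause was not tested. Quantile normalization gave 75 genes for Ac4ManNLev, 21 for C1OH-Ac3ManNAc (12 rose, against 5 of 7), 91 for C1OH-But3GlcNAc, 54 for C1OH-But3ManNAc, 0 for C6OH-But3ManNAc, 0 for C1OH-But3GlcNAc against C1OH-But3GalNAc and an overlap of 59. A pseudocount of 1 gave 0 for C1OH-But3GlcNAc against C1OH-But3GalNAc and 1 for C1OH-But3ManNAc against C6OH-But3ManNAc, while with a pseudocount of 64 all counts stayed within 1.5 times (37 for Ac4ManNLev, against 25). No filter gave 2 for C1OH-Ac3ManNAc, 27 for C1OH-But3GalNAc, 0 for C6OH-But3ManNAc, 0 and 1 for those contrasts between analogs and an overlap of 21, and the 60th percentile filter gave 40 for Ac4ManNLev. No intensity trend gave 13 for Ac4ManNLev, 0 for C1OH-Ac3ManNAc, 17 for C1OH-But3GalNAc, 7 for C1OH-But3GlcNAc (5 rose, against 21 of 56), 0 for C1OH-But3ManNAc, C6OH-But3ManNAc and both contrasts between analogs, and an overlap of 6. Array weights gave 76 for Ac4ManNLev, 89 for C1OH-But3GalNAc, 2 for C1OH-But3ManNAc, and 0 and 1 for those contrasts between analogs. The mean of probe sets gave 15 for C1OH-But3ManNAc and 0 for C1OH-But3GlcNAc against C1OH-But3GalNAc. The bright-end covariate gave 54 for Ac4ManNLev, 2 for C1OH-Ac3ManNAc, 9 for C1OH-But3ManNAc, 0 for C6OH-But3ManNAc, and 0 and 1 for those contrasts between analogs. It kept 67 of the 89 list calls, ended 17 and reversed 5, with medians of the ribosomal list of -0.0114 with C1OH-Ac3ManNAc, -0.0404 with C1OH-But3ManNAc, -0.0231 for C1OH-But3ManNAc against C6OH-But3ManNAc and 0.0246 for Ac4ManNLev against C1OH-Ac3ManNAc, and of oxidative phosphorylation of -0.0393 with C1OH-Ac3ManNAc. The overlap was 4 at an adjusted p of 0.01, and 13 of the 89 list calls passed with an estimated correlation.

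Leaving out each array in turn gave 0 to 26 genes for Ac4ManNLev, 0 to 9 for C1OH-Ac3ManNAc, 13 to 44 for C1OH-But3GalNAc, 8 to 68 for C1OH-But3GlcNAc, 0 to 23 for C1OH-But3ManNAc and 0 to 1 for C6OH-But3ManNAc against vehicle. Between analogs it gave 0 to 4 for C1OH-But3ManNAc against C6OH-But3ManNAc, 0 to 1 for C1OH-But3ManNAc against C1OH-Ac3ManNAc, 0 to 1 for Ac4ManNLev against C1OH-Ac3ManNAc, 0 for C1OH-But3ManNAc against C1OH-But3GlcNAc, 0 to 6 for C1OH-But3ManNAc against C1OH-But3GalNAc and 0 to 6 for C1OH-But3GlcNAc against C1OH-But3GalNAc. The list calls ran from 80 to 106 and the overlap from 13 to 25; 37 of the 89 list calls passed whichever array was left out, and 12 passed under every one of 26 settings. Signal over background limits the dim genes: the 40th percentile signal of the arrays was 21.5 to 26.4, near the 16 added before taking logs, so changes of genes below that level are compressed. On simulated data, 42.4% of changes of 0.5 on the log2 scale and 80.2% of changes of 1 were found in a contrast against vehicle, with a false share of 5.69%, and 31% and 76.1% in a contrast between analogs, with a false share of 5.05%.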

Other observations

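The genes of this part and the tests between analogs were chosen after the values were seen. CAVIN3, a coat protein of caveolae, fell with 3 analogs, with log2 changes of -0.60 to -0.25 over the 6 vehicle contrasts, and MATN2, a matrix protein, fell with 3 (-0.71 to 0.05). STEAP1, a membrane metalloreductase, rose with 3 (0.28 to 0.59), RHOB, a small GTPase of the stress response, with 3 (0.19 to 0.53), and THBD, the thrombin receptor thrombomodulin, with 2 (0.25 to 0.65). NQO1 and AKR1C3 rose with 4 analogs and had their lowest log2 changes at -0.20 and -0.07, both with C6OH-But3ManNAc.

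Genes that rose or fell with C1OH-But3GlcNAc or C1OH-But3GalNAc were read between other analogs too. Between C1OH-But3ManNAc and C1OH-Ac3ManNAc, at 30 and 100 µM, the 45 genes that rose had a median difference of 0.17 (39 above 0, camera p = 0.00067 with an estimated correlation) and the 48 that fell one of -0.11 (35 below 0, p = 0.0149). Between Ac4ManNLev and C1OH-Ac3ManNAc, at 75 and 100 µM, the same 45 and 48 genes had medians of 0.10 (32 above 0, camera p = 0.0318 with an estimated correlation) and -0.06 (31 below 0, p = 0.071), with p-values from limma's camera.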
